A study of Mus musculus with 2 samples.

How the data were processed

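Total RNA sequencing libraries from hippocampus of 10-day-old B6CASTF1/J mice were used, 2 biological replicates of 1 group per the labels. Running numbers in the labels differ between the libraries and each label names 3 males; whether each library is a pool is not spelled out. The labels give both libraries the same sex, and the sex-linked genes of replicate 2 differ from its label, so it is called the library labelled male, replicate 2.

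Gene and transcript tables were deposited with expected counts and TPM, derived from transcriptome alignments to mm10 with the GENCODE M21 annotation, per the deposited descriptions. The deposited expected counts are whole numbers in some rows and not in others, and were not normalized. The deposited TPM values are scaled to the same total in each library over all rows, spike-ins included. A further deposited transcript table holds estimated counts and TPM derived from the FASTQ file. The tools are not given in the sources used here; the column names are those RSEM and kallisto write. For long transcripts the effective length was below the length by 99 in the first table and by a median of 352 and 356 in the other.

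Gene identifiers were matched to GENCODE M21, and all 55536 annotated genes matched. Sums of FASTQ-based transcripts per gene gave the FASTQ-based gene values, and 86 genes had no such row. The gene table also holds 97 spike-in rows, 1 of them phiX, and 26248 rows named only by a number, which held 2.81e-05% and 2e-05% of counts and were left out of library sizes and tests.

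The depth was 32035705 and 29747193 expected counts. Expected counts were rounded to whole numbers before tests. Scaling used TMM in edgeR 4.0.16 under R 4.3.3 on genes kept by filterByExpr, and the biological coefficient of variation came from estimateDisp with an intercept only. Genes with a mean count of at least 100 were compared between the libraries by a two-sided exact binomial test with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and an absolute log2 ratio of at least 1. Log2 ratios use a prior count of 0.5, and folds against 0 counts use a floor of 3 counts. Counting intervals are exact Clopper-Pearson intervals at 95%. Reads carry no molecular identifiers in the sources used here, so intervals and floors cover counting error only. Strand use in counting is not given in the sources used here, so overlapping antisense genes may share reads.

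List shifts are the median log2 ratio of members with a mean count of at least 10 as a percentile among 10000 random lists of equal size drawn from 20 expression bins. Pair ratios were set against the change in ratio between the libraries of 10000 random gene pairs with a TPM of at least 1. The routes were compared over genes with a mean TPM of at least 1 by either, with a pseudocount of 0.1. Parents of processed pseudogenes with a mean count of at least 50 were assigned by BLAST 2.17.0 against protein-coding transcripts, with at least 90% identity over at least 50% of the length. Other steps used Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

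On simulated data with 200 changed genes the binomial test called 100% of genes changed 3-, 4-, 6- and 8-fold and 0 unchanged ones among 12888 tested, with counting noise only. A coefficient of variation of 0.05 put into 17960 genes was recovered as 0.0498. That is below the 0.0688 estimated for these libraries, and no reads shared between near-identical rows were simulated. The simulation therefore does not cover calls that arise from shared reads.

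The 32 gene lists, 14 pairs, 15 isoform genes, tests and most alternatives were fixed before the data were examined. Of these, 2 pairs and some single genes are not reported here, and list medians and counts include all members. Named genes were the 20 with the highest mean TPM, the 4 highest and the lowest member of each list, all pairs, the 10 called genes with the largest log2 ratio in each direction, and the 8 genes furthest apart between routes in each direction with a TPM of at least 5. Other genes named were chosen after their values were seen. Alternatives were another scaling, other filters, pseudocounts, the FASTQ-based table and single libraries. Leaving out chromosomes X and Y, restriction to protein-coding genes and centring of the route ratios were added after seeing the data. Alleles of the hybrid were not analysed here.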

Results

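Total RNA was sequenced from hippocampus of B6CASTF1/J mice, the first-generation hybrid of the C57BL/6J and CAST/EiJ strains, at 10 days of age. The labels describe 1 group with 2 biological replicates, each labelled male and started from 300 ng of RNA. Spike-in RNA was added, and the spike-in entry of the labels names stranded libraries with reduced ribosomal RNA. The expected counts summed to 32035705 in replicate 1 and 29747193 in replicate 2. With 1 group there was no comparison between conditions, so the levels, the spread between the libraries and the difference between the 2 libraries are given.

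The sex-linked genes differed from the label in 1 library. Xist, the non-coding RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254, mm10), had 25 counts in replicate 1 and 30841 in the library labelled male, replicate 2. That is 1334-fold higher, with an exact 95% counting interval of 904 to 2062. Ddx3y, an RNA helicase gene of chromosome Y (1260771 to 1286629), had 2164 and 0 counts, at least 667-fold lower in replicate 2 against a floor of 3 counts per library. Eif2s3y, a translation initiation factor gene of chromosome Y, had 1302 and 0 counts, at least 401-fold lower against the same floor. For Ddx3y and Eif2s3y the exact 95% counting intervals start lower, at 542- and 326-fold. Kdm5d had 991 and 2 counts, a ratio of 458 with an interval of 127 to 3789. Uty had 764 and 1, a ratio of 707 with an interval of 126 to 27942. Tsix, the antisense partner of Xist, had 45 and 45.5 counts. Each difference between the libraries given from here on is therefore also a difference between a library with counts on these 4 Y-linked genes and one with 2 or fewer on each, from alignments.

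Nuclear protein-coding genes held 80.3% ± 0.0964 of the expected counts (SD, n = 2). Mitochondrial genes held 8.06% ± 0.147, and their ribosomal RNAs mt-Rnr1 and mt-Rnr2 alone 6.34% ± 0.0832 of all counts. The neighbouring rows Gm26917 and Gm42418 on chromosome 17, annotated as long intergenic RNAs, held 2.80% ± 0.0868, and RefSeq lists Gm42418 as a synonym of the ribosomal RNA pseudogene Rn18s-rs5. Long intergenic non-coding RNA genes held 4.56% ± 0.0107 with those 2 rows and 1.76% ± 0.0761 without them, and pseudogenes 1.26% ± 0.0163. Genes picked by symbol as replication-dependent histones, a class whose transcripts lack a poly(A) tail, held 0.0806% ± 0.00712. The 71 genes picked included processed pseudogenes such as Hist3h2bb-ps and Hist1h2al, so the class is not pure. On the TPM scale the highest rows were short structural RNAs. Rn7s1 and Rn7s2, the RNA of the signal recognition particle, were listed with identical values of 127773 ± 2846 TPM, so their reads were shared and the split between them is uncertain. Rn7sk, a regulator of transcription elongation, stood at 61188 ± 5060.3. The ribonuclease P RNA Rpph1 reached 8223 ± 254 and Malat1, a nuclear RNA, 3474 ± 98.8. Gm28661, Gm10925 and Gm28437, annotated as unprocessed pseudogenes side by side on chromosome 1, were also among the 20 highest rows, at 6634, 5084 and 3365 TPM. In replicate 1 they held 83800, 64376 and 52242 of the 408504 expected counts on pseudogenes. Their FASTQ-based counts there were 55229, 12832.5 and 32829, so their counts and the pseudogene share are uncertain. The origin of their reads was not tested. Among nuclear protein-coding genes the elongation factor gene Eef1a1 led with 2044 ± 10.8 TPM, followed by Actb at 1874 ± 27.1 and the tubulin gene Tuba1a at 1701 ± 139.7.

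At a TPM of 1 or more, 15085 genes were detected in both libraries, 15684 in replicate 1 and 15635 in replicate 2. Protein-coding genes made up 13075 of those found in both, long intergenic non-coding RNA genes 278 and pseudogenes 652.

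Among the lists of neuron types, excitatory neuron genes had the highest median. Of the glutamatergic list, 8 of 8 genes were detected in both libraries, with a median of 84.9 ± 1.18 TPM (SD of the library medians, n = 2). Camk2a, a postsynaptic kinase, stood at 835 ± 66.7 TPM, the calmodulin-binding protein gene Nrgn at 672 ± 27.4 and the vesicular glutamate transporter gene Slc17a7 at 529.9 ± 29.3. For GABAergic neurons 16 of 16 genes were detected, with a median of 32.9 ± 0.728 TPM. The neuropeptide genes Sst and Cck led at 214 ± 5.86 and 205 ± 3.07 TPM, the glutamate decarboxylase gene Gad1 stood at 94.1 ± 0.255, and Dlx5 was lowest at 2.83 ± 0.297. Dentate granule cell genes had 7 of 8 members detected and a median of 14.7 ± 1.15 TPM, led by the homeobox gene Prox1 at 48.6 ± 1.32. CA1 pyramidal cell genes had 5 of 5 detected with a median of 33.1 ± 5.06 TPM, and CA2 and CA3 genes 11 of 12 with 17.9 ± 1.40 TPM. Mpped1 led the former at 76.1 ± 2.75 TPM and Pcp4 the latter at 127 ± 6.90.

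The immature neuron list had 9 of 9 genes detected with a median of 34.6 ± 0.481 TPM, and its tubulin gene Tubb2b stood at 757 ± 72.2 TPM against 73.2 ± 10.02 for the microtubule protein gene Dcx and 2.53 ± 0.269 for Eomes. Axon and neurite growth genes had 7 of 7 detected with a median of 363 ± 41.7 TPM, with Stmn2 at 762 ± 64.5 and Gap43 at 405 ± 39.1. Cell cycle genes had 11 of 12 detected and a median of 3.44 ± 0.622 TPM, with the proliferation marker Mki67 at 4.54 ± 0.106. Radial glia and stem cell genes had 9 of 9 detected and a median of 25.96 ± 4.50 TPM, led by Fabp7 at 276 ± 6.47.

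Among glia, the astrocyte list had 11 of 11 genes detected with a median of 119 ± 7.24 TPM, led by the glutamate transporter gene Slc1a2 at 695 ± 47.6 TPM. Oligodendrocyte precursor genes had 9 of 9 detected with a median of 21.02 ± 1.34 TPM, and Olig1 stood at 72.3 ± 1.80. The myelin list had 10 of 12 detected with a median of 9.68 ± 3.61 TPM. Mbp, a major myelin protein gene, ranged from 89.2 TPM in replicate 1 to 161 in replicate 2, and Opalin stood at 0.17 ± 0.0283. Microglial genes had 11 of 11 detected with a median of 14.5 ± 1.03 TPM. Endothelial genes had 8 of 8 detected (9.82 ± 0.255 TPM), pericyte and smooth muscle genes 6 of 6 (8.78 ± 0.633 TPM), and meningeal and fibroblast genes 6 of 6 (24.7 ± 1.63 TPM). Choroid plexus genes had 3 of 9 detected in both (1.42 ± 1.05 TPM), with medians of 0.59 TPM in replicate 1 and 2.08 in replicate 2, and ependymal genes 5 of 5 (4.03 ± 1.12 TPM). Red blood cell genes had 5 of 7 detected (29.7 ± 11.1 TPM), with Hbb-bs at 261 ± 104 TPM. The median of this list was 108 TPM in the FASTQ-based table. The near-identical globin genes Hba-a1 and Hba-a2 share reads, so their split is uncertain.

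Of the lists for neighbouring regions, thalamic genes had 4 of 5 detected (6.63 ± 0.354 TPM), neocortical genes 4 of 4 (11.8 ± 0.255 TPM) and striatal genes 6 of 6 (2.02 ± 0.371 TPM). Immediate early genes, induced by neuronal activity, had 10 of 11 detected (5.95 ± 0.636 TPM), with Egr1 at 23.3 ± 4.04 TPM and Fosb at 1.17 ± 0.382.

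Of the synaptic vesicle list, 13 of 13 genes were detected with a median of 221 ± 5.47 TPM, from Stx1a at 86.00 ± 2.43 to Syp at 645 ± 13.5. Postsynaptic scaffold and adhesion genes had 14 of 14 detected (104 ± 2.42 TPM), led by Camk2b at 387 ± 6.47 and Dlg4, which encodes PSD-95, at 328 ± 8.70. Ionotropic glutamate receptor genes had 15 of 16 detected (40.2 ± 0.774 TPM), with Gria2 at 239 ± 0.75 and Grin3b at 0.115 ± 0.0778. Metabotropic glutamate receptor genes had 7 of 8 detected (16.1 ± 0.0813 TPM), led by Grm5 at 103 ± 2.56. GABA-A receptor genes had 12 of 13 detected (45.9 ± 0.997 TPM), with Gabra6 lowest at 0.095 ± 0.0495. Perineuronal matrix genes had 6 of 6 detected (46.4 ± 1.34 TPM), with Ncan at 256 ± 2.55 and Acan at 2.52 ± 0.0212. Imprinted genes, expressed mainly from the allele of 1 parent, had 24 of 26 detected (19.5 ± 1.76 TPM), led by Meg3 at 1309 ± 41.03. Nuclear and long non-coding RNAs had 8 of 8 detected (632 ± 19.3 TPM), with Neat1 lowest at 8.02 ± 0.417. Of the sex-linked list, 0 of 6 reached a TPM of 1 in both libraries.

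**Figure D1:**
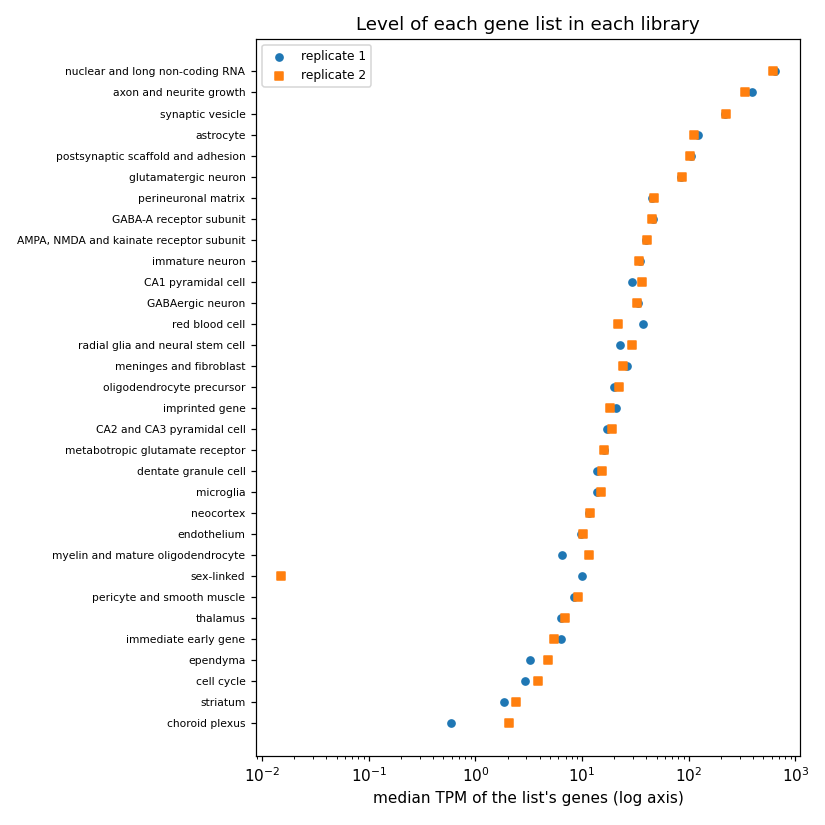
Median TPM of the genes of each list (x axis, log scale) in replicate 1 (circles) and replicate 2 (squares), with the lists ordered by their mean. Nuclear and long non-coding RNAs have the highest median at 632 ± 19.3 TPM, and the sex-linked list has medians of 10.1 and 0.015 TPM.

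The 12 gene pairs reported here, whose balance is known to move in postnatal forebrain development, were set against the spread between the libraries. For 10000 random pairs the 95th percentile of the absolute change in log2 ratio between the libraries was 0.75. Of the 12 pairs, 9 had a mean log2 ratio beyond it, so their genes differed in level by more than that change. How many random pairs have a ratio as far from 0 was not computed, so this count shows nothing particular to these pairs. With 2 libraries no test over samples was made, since the smallest two-sided sign-flip p is 0.5. The chloride transporter genes Slc12a5 and Slc12a2 had a log2 ratio of 3.33 ± 0.00049 (SD, n = 2). For the NMDA receptor subunits, Grin2a over Grin2b was -1.11 ± 0.08, with Grin2b the higher. Dlg4 over Dlg3 was 2.42 ± 0.07 and Camk2a over Camk2b 1.11 ± 0.09. Slc17a7 over Slc17a6, both vesicular glutamate transporter genes, was 4.84 ± 0.15, and Gad1 over Gad2 was 1.39 ± 0.02. Sst over Pvalb was 6.09 ± 0.16. Gfap over Vim was 1.26 ± 0.31. Mbp over Pdgfra was 1.58 ± 0.73, with 1.07 in replicate 1 and 2.10 in replicate 2. Within the benchmark lay Gria2 over Gria1 at 0.10 ± 0.04, Snap25 over Gap43 at 0.47 ± 0.19 and Scn8a over Scn2a at -0.60 ± 0.01. The benchmark covers the spread between the libraries and no gene-specific bias of TPM. From expected counts not divided by length, Gad1 over Gad2, at 0.22, and Mbp over Pdgfra, at 0.19, lay within the benchmark, and Snap25 over Gap43, at 0.87, lay beyond it. Gria2 over Gria1, within the benchmark either way, was -0.11 there. With a pseudocount of 1 TPM Scn8a over Scn2a, at -0.59, lay beyond the benchmark computed in the same way.

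**Figure D2:**
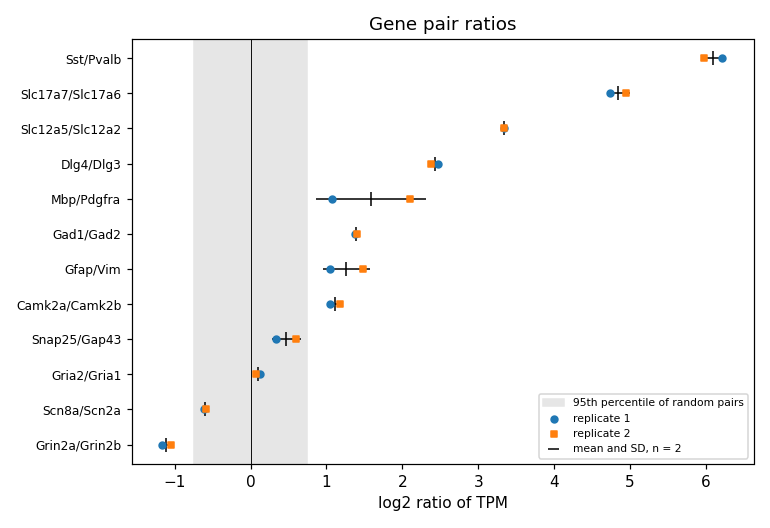
Log2 ratio of TPM (x axis) for 12 gene pairs in replicate 1 (circles) and replicate 2 (squares), with ticks and bars for the mean and SD (n = 2). The shaded band marks the 95th percentile of the change of random pairs between the libraries, 0.75, and 9 pairs have a mean outside it.

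Across the 15085 genes detected in both libraries, log2 TPM correlated with a Pearson r of 0.991 and a Spearman rho of 0.992, over genes, which are not independent replicates. The median absolute log2 ratio was 0.08. The biological coefficient of variation estimated with edgeR was 0.0688 over 17874 genes. It includes the sex-linked difference between the libraries, and without chromosomes X and Y, a choice made after seeing the data, it was 0.0576. Between the libraries 1517 of 12879 genes (11.8%) had an adjusted p under 0.05 in the two-sided exact binomial test, so they are not 1 library deposited again and were counted as 2 samples.

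Of those 12879 genes, 39 differed at least 2-fold with an adjusted p under 0.05 (two-sided exact binomial test, Benjamini-Hochberg adjustment), 19 higher and 20 lower in replicate 2. The test compares the reads of these 2 libraries, not conditions. Apart from Xist, the genes furthest higher in replicate 2 included Ttr, the transthyretin gene (chromosome 18, 20665280 to 20674321), at 8.02 and 340.1 TPM, 42.5-fold with an interval of 36.9 to 49.5. Besides the 4 Y-linked genes, lower genes included Ptgds, a prostaglandin D synthase gene, at 333 and 85.1 TPM (log2 ratio -1.99), and Hif3a at 4.55 and 1.68 (log2 ratio -1.53). Pseudogenes made up 10 of the called genes. Gm10163 had 1490.3 and 0.03 expected counts, at least 459-fold lower against the floor of 3 counts, with an exact interval that starts at 373-fold. Rps4x-ps had 2.80 and 285, Gm13680 7.28 and 250.2, Rbm3-ps 11.96 and 198, and Gm9616 60.9 and 458. Gm10240 and Gm13370 had identical values of 282 and 977. Each of these matched the transcript of a protein-coding gene at 97.85% identity or more, so their counts are uncertain. Rpl21 was the best match of Gm10163, Gm10240 and Gm13370, and Rps4x that of Rps4x-ps, Gm13680 and Gm9616. From FASTQ-based counts Rps4x-ps (0 and 298), Gm13680 (8.83 and 242) and Gm9616 (3.14 and 316) were higher in replicate 2 as well. Rps4x itself had a log2 ratio of -0.31 from alignments. Counts of the small nuclear RNA Gm24497 were also not whole, at 2104 and 0.89, and are uncertain in the same way. Myl12b, Ptp4a1 and Fam220a have 2 gene identifiers each. For Myl12b the one called had 47.3 and 378 counts and the other, ENSMUSG00000034868.9, 3426 and 2852. Both Fam220a identifiers were called, in opposite directions, and from FASTQ-based counts the one higher in replicate 2 had a log2 ratio of -0.0487. Ptp4a1, Gm10240 and Gm13370 were tested and not called from FASTQ-based counts. Further called genes had a mean FASTQ-based count under 100 and were not tested there. Gm24497 and the pseudogene Gm10095, called at 183 and 19.1 expected counts, had 0 FASTQ-based counts in both libraries, and Myl12b had under 1. Gm10163 had 145 and 0, and Rbm3-ps 4.796 and 0, the opposite direction to its expected counts. Restricted to protein-coding genes the test called 22 genes, and with a mean count of at least 10 it called 175.

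**Figure D3:**
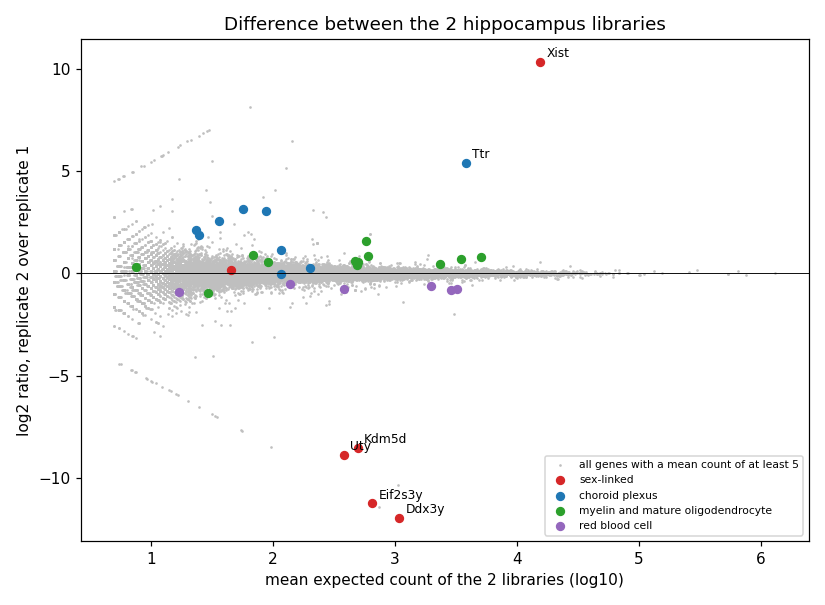
Log2 ratio of replicate 2 over replicate 1 (y axis) against the mean expected count of both libraries (x axis, log10), for genes with a mean count of at least 5 (grey), with 4 lists in colour. Xist lies at 10.35 and Ttr at 5.41, and the 4 Y-linked genes lie at or below -8.52, where values depend on the prior count of 0.5.

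Marker lists were compared with 10000 random lists matched on expression, as a description of these libraries. Of 32 lists, 14 lay outside the central 95%. Choroid plexus genes were higher in replicate 2, with a median log2 ratio of 2.13 above all random lists. 8 of 9 members were higher, and of 4 tested, Ttr and Sostdc1 passed, 2 adjusted over the list alone and 2 over all genes. The water channel gene Aqp1 had 12 and 101 counts, and Kl had 193 and 211. Myelin genes had a median of 0.60, above all random lists, and 8 of 8 tested were higher at an adjusted p under 0.05, 8 adjusted over the list alone. Of these Mobp alone passed 2-fold, with a log2 ratio of 1.60, beside 0.87 for Mag and 0.79 for Mbp. Red blood cell genes were lower, at -0.78, below all random lists, with 5 of 5 tested lower and 5 adjusted over the list alone. Immature neuron genes (-0.16) and axon growth genes (-0.16) were below all random lists, with 4 of 9 tested lower and 1 higher in the former and 7 of 7 lower in the latter. Adjusted over the list alone, 6 and 7 differed. Smaller shifts of the list median were found for ependymal (0.46), immediate early (0.21), thalamic (0.17), microglial (0.12) and oligodendrocyte precursor genes (0.11), each above the range. Past the adjusted p over all genes were 0 of 2 tested ependymal members, 0 of 4 thalamic, 2 of 9 immediate early and 3 of 9 microglial ones, each higher where it passed, and of 9 oligodendrocyte precursor genes 3 higher and 2 lower. Adjusted over the list alone the counts were 0, 2, 3, 3 and 6. Meningeal (-0.15), long non-coding (-0.08) and imprinted genes (-0.07) had medians below it. Over all genes 3 of 5 meningeal members passed lower, 6 of 8 long non-coding ones lower and 2 higher, and 8 of 23 imprinted ones lower and 2 higher, and adjusted over the list alone 4, 8 and 11 differed. The remaining list outside the range was the sex-linked one, given gene by gene at the start. The other 18 lists lay within the range, with medians from -0.04 for the GABAergic to 0.10 for the neocortical list. Members passed over all genes there too, from 0 of 8 cell cycle genes to 11 of 14 postsynaptic ones (7 higher, 4 lower). Of 11 astrocyte genes 5 passed higher and 3 lower. The number of passing members alone therefore does not mark a shifted list. From FASTQ-based counts the thalamic list, at 0.12, lay inside the range and the dentate granule cell list, at 0.10, outside it. With protein-coding members off chromosomes X and Y only, chosen after seeing the data, the imprinted list (-0.04) lay inside and the CA2 and CA3 list (0.10) outside.

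**Figure D4:**
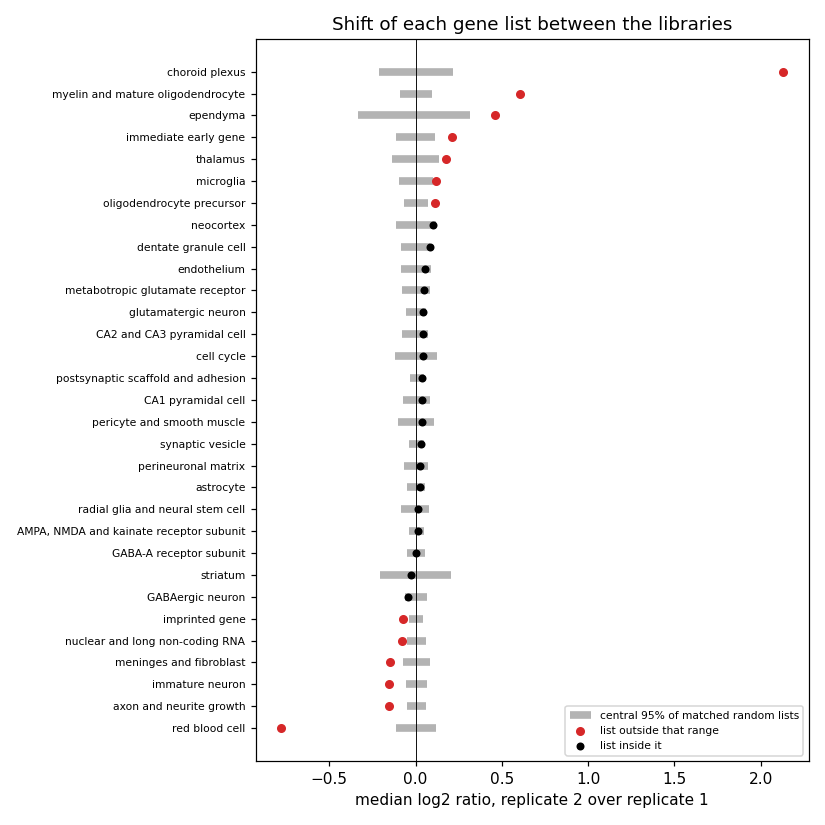
Median log2 ratio of each list, replicate 2 over replicate 1 (x axis), with grey bars for the central 95% of matched random lists; the sex-linked list is left out because its median depends on the prior count. Choroid plexus lies at 2.13, myelin at 0.60 and red blood cell at -0.78.

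Each library was quantified by 2 routes, from transcriptome alignments and from the FASTQ file. Over 18483 genes the TPM of both routes correlated across genes with a Spearman rho of 0.895 in replicate 1 and 0.895 in replicate 2. Pearson's r was 0.772 and 0.773 on log2(TPM + 0.1). FASTQ-based TPM was higher by a median of 1.55-fold in replicate 1 and 1.55-fold in replicate 2. With FASTQ-based TPM 18 of the 32 list medians were over 1.5 times higher and 0 over 1.5 times lower. TPM are scaled to a fixed total. Rn7s1 and Rn7s2, at 127773 TPM each from alignments, and Rn7sk, at 61188, had at most 0.863 TPM in the FASTQ-based table. Their near absence there raises the TPM of all other genes, so a higher list median need not be particular to that list. How much of the 1.55-fold this makes up was not computed. More than 2-fold apart in both libraries were 3485 genes, 2873 higher and 612 lower from the FASTQ file. Centred on the median ratio, an alternative chosen after seeing the data, 1394 were higher and 693 lower. The largest differences were short RNAs. Rn7sk, both Rmrp identifiers and mt-Atp8 had 0 estimated counts in the FASTQ-based table, and Rn7s1 and Rn7s2 had at most 1. In the other direction Gm26905 had 4 and 4 expected counts against 12018 and 11064 FASTQ-based ones. Gm47283, annotated on chromosome Y, had 0 expected counts in both libraries and 2341 and 1828 FASTQ-based ones. Unlike the 4 Y-linked genes above, it was not near 0 in replicate 2 there, and the origin of its reads was not tested.

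Of 9799 genes with a TPM of at least 5 and at least 2 transcripts, 6754 (68.9%) had the same highest transcript in both libraries and by both routes. Between the libraries alone the share was 91.5% from alignments and 89.4% from the FASTQ files. App, the amyloid precursor protein gene, was dominated by 1 transcript with 91.2% ± 0.133 of its alignment-based TPM (SD, n = 2), Mapt, which encodes tau, by one with 84.4% ± 3.67, and Kif1b by one with 81.9% ± 0.753. The leading share was 72.3% ± 0.796 for Snap25, 65.6% ± 0.132 for Camk2a, 60.5% ± 3.41 for Clta and 52.9% ± 0.644 for Gria2. It was 43.8% ± 0.027 for Grin1, 40.3% ± 0.0931 for Ncam1 and 34.8% ± 1.01 for Ntrk2. For Mbp the leading transcript differed between the routes, and for Cdc42 and Homer1 it differed between the libraries in the FASTQ-based table.

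Of 96 spike-in controls, 58 had counts in both libraries, and they held 0.358% and 0.359% of the counts. Among the 24 with a mean count of at least 100, the SD of the log2 ratio between the libraries was 0.13.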

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

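The tests of the X copies and of the Y-linked share, and all tests of X-linked parents, were chosen only after the result was seen. The second marker panels were chosen after the first lists had been seen and before their own values were.

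Rows named only by a number, which name no gene and enter no comparison, held 9 expected counts in replicate 1 and 5.94 in replicate 2, above the limit of 3 that a count of 0 allows.

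In the library labelled male, replicate 2, Xist was present and the 4 Y-linked genes were near 0. The FASTQ-based table gave those genes 2.39% of their replicate 1 level, which argues against an error of 1 quantification, though Kdm5d and Uty kept 74.4 and 45.7 counts there. The upper 95% limit from alignments was 0.182%, under the 10% set as the bound for a pool with males. The X copies Ddx3x, Eif2s3x, Kdm6a and Kdm5c had a median log2 ratio at percentile 99.9 of matched X-linked lists, so tissue of female animals under a male label is a candidate explanation. Sex cannot be separated from any other difference between these 2 libraries.

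Choroid plexus genes were higher in replicate 2. Reassigned reads of Ttr are argued against by its FASTQ-based log2 ratio of 5.39, and a general excess of non-neural tissue by the second leptomeninges panel, at -0.30. Choroid plexus tissue taken along stays open: a second panel had a median of 0.82, between the bounds of 0.5 and 1 set beforehand, with 9 of 10 members higher. Car12 and Cab39l, at 11.7 and 7.74 TPM in replicate 1 already, could hide a small share, with log2 ratios of 0.33 and 0.44. Neighbouring neural tissue was not tested and stays open, with myelin (0.60), ependymal (0.46) and thalamic list medians (0.17) also higher, where 8 of 8, 0 of 2 and 0 of 4 tested members passed over all genes, the last list inside the random range from FASTQ-based counts (0.12), and striatal (-0.03) and neocortical lists (0.10) inside it; no biological explanation was tested.

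Processed pseudogenes differed between the libraries. An unstable split of reads between near-identical copies stays open: the 257 with an autosomal parent had a median absolute log2 ratio of 0.149, below the bound set beforehand, but such a median excludes nothing for the 7 of them at 1 or more. The 3 called pseudogenes of Rpl21 moved in opposite directions and summed to 2053 and 1954 counts. The 10 with an X-linked parent had a median of 0.543 (one-sided permutation p = 0.00021) and 0.397 without those of Rps4x, and 1 value per parent gave a permutation p of 0.00616 over 7 X-linked and 207 autosomal parents, but this includes the called pseudogenes that prompted the test. Without the parents of called pseudogenes the medians were 0.227 for 5 X-linked and 0.143 for 249 autosomal ones (one-sided permutation p = 0.202), so X-linked parents stay open too, and neither the CAST allele nor a biological explanation was tested.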

How the results depend on the processing

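Alternatives added after seeing the data were leaving out chromosomes X and Y, protein-coding genes only and centring. No paired analysis was possible because there is 1 group. The biological coefficient of variation of 0.0688 was 0.0837 with no filter, 0.0672 from FASTQ-based counts, 0.0576 without chromosomes X and Y and 0.0558 for protein-coding genes. The 39 genes differing between the libraries became 175 with a mean count of at least 10 and 22 for protein-coding genes, where more and fewer genes were tested; from FASTQ-based counts 33 were called, 20 of them shared. Split by direction, 13 were higher and 20 lower there, and 7 and 15 for protein-coding genes. Genes more than 2-fold apart between the routes went from 3485 to 6285 with no filter and 2087 when centred. Genes with 1 highest transcript throughout went from 6754 to 3942 of 4233 with a 2-fold lead, where fewer genes were tested. From FASTQ-based counts the log2 ratio of Fam220a turned to -0.0487. For this and for the coefficients of variation the cause was not tested. For the routes no cause was tested, and the fixed total of TPM accounts for a part that was not measured. List medians moved by more than the SD between the libraries in 30 of 32 lists with FASTQ-based TPM (29 higher). Leaving out 1 of 2 libraries moves a mean of 2 values by less than their SD by construction, but a list median of gene means has no such bound. Without replicate 1, 3 lists moved by more than the SD, the endothelial (10.11 TPM), striatal (2.395) and sex-linked ones (0.015). Without replicate 2, 1 list did, the meningeal one (26.38 TPM). Rescaling without mitochondrial and spike-in rows multiplies every gene of a library alike, so it tests nothing. The 15085 detected genes became 21328 at a TPM minimum of 0.1 and 10895 at 5. They were 17033 with FASTQ-based TPM. TPM rescaled to nuclear protein-coding genes gave 13973, which can only be a count of those genes, since this rescaling lowers no TPM. It stands beside the 13075 protein-coding genes of the main count and is not a drop from 15085. Without 1 replicate each, detected genes ranged from 15635 to 15684. Coefficients of variation, differing genes and list shifts need both libraries and have no value without 1 of them. Depth limits low genes, which the main test left out below a mean count of 100.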

Other observations

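The called genes Fmod, Ccn2 and Slc6a20a lie outside the fixed lists, were chosen here after their values were seen, and were lower in replicate 2. Fmod, a collagen-binding proteoglycan gene, had 280 and 93 counts (log2 ratio -1.47), the matricellular gene Ccn2 282 and 120 (-1.12), and the amino acid transporter gene Slc6a20a 499 and 228 (-1.02). The 445 X-linked genes with a mean count of at least 100 had a median log2 ratio of -0.03. Firre, an X-linked non-coding RNA gene, was lower in replicate 2, with 1724 and 605 counts and a log2 ratio of -1.40. The 4 small nucleolar RNA rows Rnu3b1 to Rnu3b4 held identical values of 128 and 334 counts, so their reads are shared.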
